A study of Mus musculus with 6 samples.

How the data were processed

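Small RNA was sequenced from extracellular vesicles of primary hepatocytes of ApoE knockout mice fed chow (Chow-EV, 3 libraries) or the HFHC diet (HFHC-EV, 3 libraries). Per the labels' protocols, RNA was taken up with an exosome RNA kit, small RNA was cut from a denaturing gel, ligated to adapters, reverse transcribed and amplified by PCR. The submitters' processing notes name Bowtie2 and the genome build GRCm38.p6. The Bowtie2 version, the miRNA annotation, the counting of reads that match several miRNAs, adapter trimming and the treatment of PCR duplicates are not given in the sources used here. Without molecular identifiers, reads are not independent molecules, and near-identical miRNAs such as the let-7 members may share reads.

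The deposited values are RPM (per-million reads), 1 table per library with the same 474 miRNAs in each, 69 of them under provisional names that the authors gave; such miRNAs are described without those names. What the authors counted in the denominator is not stated, and the columns sum to 1375 to 3441, so it is wider than the listed miRNAs. In each library the low RPM values were whole multiples of 1 step (100% of them within 0.1 of a read), so whole reads were recovered by dividing by that step, and the denominators came to between 19114300 and 20122200 reads. Over all values above 0, 100% came out whole within the same tolerance in 5 libraries and 99.1% in HFHC-EV replicate 3, where 3 values of at least 200.8 did not. The design fixed before the data were examined had assumed counts, with edgeR as the main test; since the files held RPM, the test that the design named for normalized values was used instead, and the count tests on recovered reads became alternatives. Every column was mapped to its sample through the series' records.

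The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(RPM + 1) over miRNAs with a mean of at least 1 RPM, with diet as the only term, no block, and Benjamini-Hochberg adjustment at 0.05. The main scale is the authors' own, with no further scaling. The files give 104 such miRNAs. miR-30a-3p, under that filter, was taken from the same fit without it. miRNA lists (19, fixed before the data were examined, covering families, cell-type markers and literature groups) were tested with camera (correlation 0.01) where 3 or more members were tested, with an estimated correlation and fry beside it. Hairpins with both products tested were compared with limma's diffSplice. Values of single libraries were compared with 2-sided exact permutation tests (scipy 1.17.1), whose smallest p for 3 against 3 is 0.1. Detected miRNAs were counted after thinning to 27673 reads, as the mean of 100 seeded draws. A share in 1 library has an exact Clopper-Pearson 95% interval, and a miRNA without reads is bounded by 3 reads over its group. With 27673 to 65775 miRNA reads per library, a mean of 1 RPM stands for about 20 reads. Of the 73 miRNAs with a mean of 50 or more reads, 18 varied within both diets by no more than counting error.

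The miRNAs given by name follow a rule fixed before the data were examined: among called miRNAs whose 3 values of one diet all lie above those of the other after TMM scaling, the 10 with the largest absolute log2 fold change in each direction; the 10 most abundant; miR-30a-3p and miR-122-5p; of each list the called members up to 4, or otherwise its 2 most abundant; and hairpins with a changed arm balance. Others are said to be chosen after their values were seen. Hairpin positions and overlapping genes come from GENCODE M21 on GRCm38, by hairpin name, which does not tell apart several hairpins of 1 mature product.

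No label says that a replicate number marks a shared mouse, litter or day, so the numbers were checked in the data. Deviations from the diet means over the 104 miRNAs correlated at 0.945, 0.894 and 0.946 between libraries with the same number and at −0.819 to 0.0265 between others, so the numbers pair the samples, and the fit with the replicate block is given where it changes a call. The limma fit with the block (RPM) had 2 residual degrees of freedom and 208 in total, against 5.18 in total without it. Its p therefore rest on a variance pooled over the tested miRNAs, not on that of each miRNA. No pair of libraries agreed within sampling noise (chi-square per degree of freedom at least 12.3).

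Alternatives fixed beforehand were RLE, total and upper-quartile scaling, TMM without the 5 most abundant miRNAs, no filter, a mean of 50 or more reads, pseudocounts of 0.1 and 10, DESeq2 (1.42.0) and voom on recovered reads, robust variance, other thresholds, the block, and leaving out each library. TMM scaling, edgeR (4.0.16) on recovered reads with and without block or with the authors' denominator, TMM with the block, the correlations over between-diet pairs of different numbers and on log2(RPM + 1), and leaving out both libraries of a number were added after seeing the data. The edgeR test called 1 miRNA higher and 5 lower, and 22 and 4 with the authors' denominator.

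The fits were tested on simulated data made for 104 miRNAs from the real means, with 26 changed in each of 20 draws of the HFHC-EV against Chow-EV comparison. Without the block 13.8% of the 2-fold and 50.0% of the 4-fold changes were recovered with 0 false calls, and with it 83.8% and 97.3%, with 0.45 false calls per draw. The simulated means were those of each replicate number, shared by both diets, and the dispersion came from the count fit with the block. The advantage of the block was thus built in and does not rank the fits on the real data. No shift common to all miRNAs was simulated.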

Results

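Extracellular vesicles (EVs), the membrane-bound particles that cells release, were collected from primary hepatocytes of ApoE knockout mice, a strain prone to high plasma cholesterol and atherosclerosis. The mice had been fed chow or the diet that the labels call HFHC, and the miRNAs carried by the EVs were sequenced. The study held 3 libraries of EVs from hepatocytes of chow-fed mice (Chow-EV) and 3 from those of HFHC-fed mice (HFHC-EV), which the labels call biological replicates numbered 1 to 3; how many mice stood behind each library is not given. The deposited values were RPM (reads scaled to a per-million total), with 474 miRNAs listed in every library. One read was worth about 0.05 RPM, so each library rested on a denominator of 19114300 to 20122200 reads, of which the listed miRNAs took between 0.138% and 0.344%. This left 27673 to 65775 miRNA reads per library. No read was recorded for 52 of the miRNAs, and 104 had a mean of at least 1 RPM and entered the tests, which together held 97.3% of all miRNA reads. Intervals and floors below cover counting error only.

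The first question was whether the amount and diversity of miRNA in hepatocyte EVs differed between the diets. The let-7 family, a conserved group linked to differentiation, dominated both kinds of EV, with 46.6 ± 6.81% of the miRNA reads in Chow-EV and 44.7 ± 6.72% in HFHC-EV (mean ± SD, n = 3 each). let-7c-5p was the most abundant miRNA at 192 ± 23.2 RPM in Chow-EV and 319 ± 29.9 in HFHC-EV, followed by let-7a-5p, let-7f-5p and let-7b-5p. miR-122-5p, the most abundant miRNA of hepatocytes, was a minor component of all 6 libraries and varied with the replicate number. It made up 0.689% of miRNA reads in Chow-EV replicate 1 (exact binomial 95% confidence interval 0.598 to 0.789) and 0.581% in HFHC-EV replicate 1 (0.514 to 0.655), against 0.0542% (0.0303 to 0.0894) and 0.0522% (0.0323 to 0.0798) in the other Chow-EV libraries and 0.0426% (0.0253 to 0.0673) and 0.0304% (0.0186 to 0.0470) in the other HFHC-EV libraries. Its share differed between the diets by −0.047 percentage points (means 0.218% in HFHC-EV and 0.265% in Chow-EV; 2-sided exact permutation p = 0.5), less than the spread between libraries.

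The summed miRNA signal was higher in HFHC-EV, with 2683 ± 665 RPM against 1662.5 ± 371 in Chow-EV (n = 3 each), and it was higher in all 3 pairs of libraries with the same number. In recovered reads the difference of mean log2 totals was 0.65 (2-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). After thinning every library to 27673 reads, 234 ± 42.5 miRNAs were detected in HFHC-EV and 222 ± 38.3 in Chow-EV, a difference of 11.4 that lay within the spread between libraries of a diet (exact permutation p = 0.6). The 10 most abundant miRNAs held 56.5 ± 4.86% of the signal in HFHC-EV and 58.1 ± 4.51% in Chow-EV (exact permutation p = 0.7). Within the 3 pairs of libraries with the same number, detected miRNAs were higher in HFHC-EV in 3, and the shares of the 10 most abundant miRNAs and of miR-122-5p were higher in 0 (2-sided exact sign-flip permutation p = 0.25 for each, the smallest that 3 pairs can give). The mean Pearson correlation across miRNAs, on log2(CPM + 1) with CPM the counts scaled to the miRNA reads of a library, was 0.656 within a diet and 0.638 between diets, and 5 of the 10 splits of the 6 libraries gave a difference as large (exact permutation p = 0.5). Libraries of different diets with the same replicate number correlated at a mean of 0.832, and those with different numbers at a mean of 0.541. Set against the latter alone, a comparison chosen after the values were seen, the correlation within a diet was higher by 0.115, and 1 of the 4 splits that part all 3 pairs, the real one, gave a difference as large (the highest other was −0.032). On log2(RPM + 1), also chosen after, the direction of the first difference turned: the mean correlation was 0.831 within a diet and 0.834 between diets (5 of 10 splits as large, exact permutation p = 0.5), with 0.940 for the same number and 0.782 for different numbers.

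The main comparison asked which miRNAs differed between HFHC-EV and Chow-EV. Among those higher in HFHC-EV were miR-676-3p, which went from 0.440 ± 0.0699 to 3.10 ± 0.751 RPM, miR-26b-5p, from 1.24 ± 0.195 to 5.39 ± 0.881, and miR-15b-5p, from 2.10 ± 0.428 to 7.10 ± 0.904 (n = 3 each). miR-423-3p rose from 15.2 ± 1.71 to 39.2 ± 1.94 RPM, a 2.58-fold difference, and the hepatocyte-enriched miR-192-5p rose from 4.75 ± 0.902 to 12.6 ± 0.374. In the other direction, miR-709 averaged 3.79 ± 0.802 RPM over the Chow-EV libraries (223 reads) and had no read in any HFHC-EV library, which makes it at least 72.6-fold lower there when 3 reads over the group are taken as the floor. miR-30d-5p, a 5p product of the miR-30 family, fell from 11.0 ± 0.467 to 5.50 ± 0.342.

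In limma-trend on log2(RPM + 1), 25 of the 104 tested miRNAs were higher and 5 lower in HFHC-EV at a Benjamini-Hochberg adjusted p under 0.05 (39 and 7 at an unadjusted p under 0.05). Fold changes here are on that scale, which understates the change of low miRNAs. The highest log2 fold changes among named miRNAs were 1.51 for miR-26b-5p (SE 0.163, limma adjusted p = 0.0036), 1.49 for miR-676-3p (SE 0.176, adjusted p = 0.0038), 1.39 for miR-15b-5p (SE 0.168, adjusted p = 0.0038) and 1.32 for miR-423-3p (SE 0.117, adjusted p = 0.0020). miR-192-5p, miR-183-5p, miR-99b-5p, miR-1198-5p and miR-31-5p followed, with log2 fold changes from 1.25 down to 1.08. For miR-709 the log2 fold change was −2.25 (SE 0.167, adjusted p = 0.0011) and for miR-30d-5p −0.89 (SE 0.11, adjusted p = 0.0038). The other 3 lower miRNAs and the miRNA with the highest fold change of all carry provisional names given by the authors and are described without them. The last went from 0.915 ± 0.0886 to 5.01 ± 0.376 RPM, and the lowest of the others from 5.55 ± 0.405 to 0.505 ± 0.152.

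**Figure D1:**
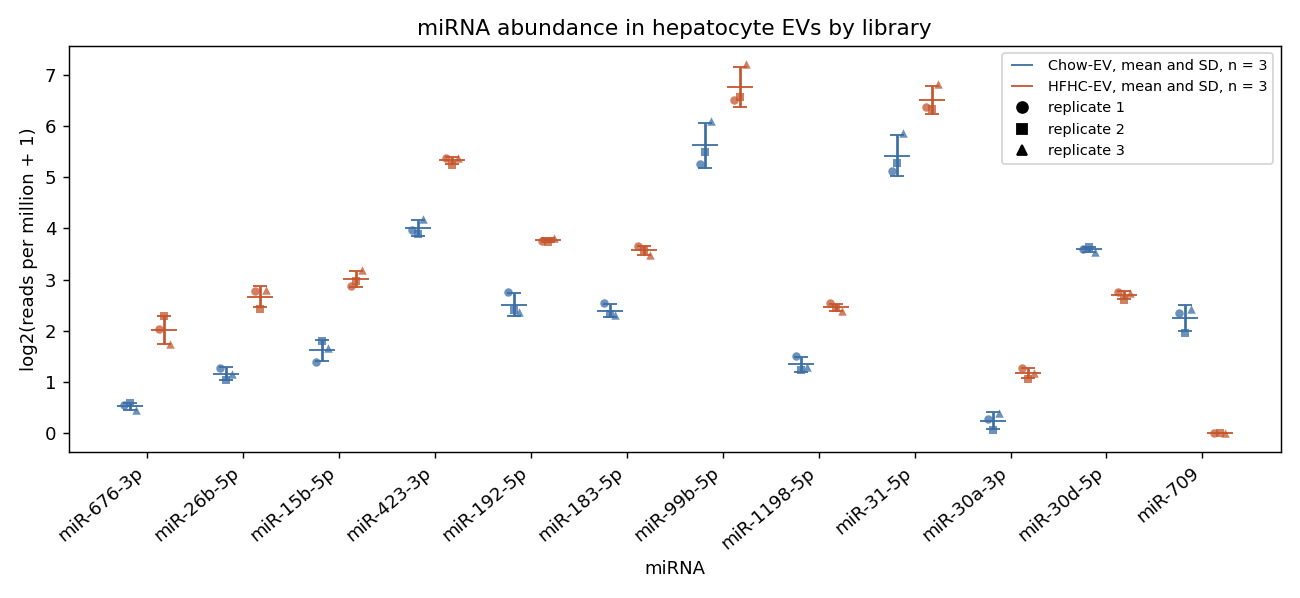
Abundance of 12 miRNAs as log2(RPM + 1) in each library, Chow-EV in blue and HFHC-EV in orange, with symbols for the replicate number and bars for the mean and SD (n = 3 per diet). From miR-676-3p to miR-30a-3p the HFHC-EV libraries lie above the Chow-EV libraries, and for miR-30d-5p and miR-709 they lie below them, with miR-709 at 0 in every HFHC-EV library.

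Most tested miRNAs were higher in HFHC-EV on the per-million scale, where the median log2 fold change was 0.51, and scaling the libraries to each other with TMM brought that median to 0.07. The median was 0.81 without Chow-EV replicate 3, 0.21 with a pseudocount of 10 and 0.042 over all 422 miRNAs with reads. Relative to this shift, 1 miRNA was higher (the provisionally named one) and 6 were lower, 5 of which were the 5 lower ones of the per-million scale. The other was miR-155-5p, an immune miRNA chosen here after its values were seen, which went from 1.92 ± 0.699 to 0.853 ± 0.397 RPM (limma adjusted p = 0.112 on that scale and 0.0352 after TMM scaling). After TMM scaling the log2 fold changes were 1.15 for miR-676-3p, 1.05 for miR-26b-5p, 0.88 for miR-15b-5p, 0.70 for miR-423-3p and 0.68 for miR-192-5p, and the adjusted p of these lay between 0.0515 and 0.205. miR-709 and miR-30d-5p had log2 fold changes of −2.51 and −1.46 on that scale (adjusted p = 0.0012 and 0.0352). The abundant let-7c-5p and let-7a-5p went from 0.73 and 0.67 in RPM to 0.084 and 0.025. With the replicate number as a block, 69 miRNAs were higher and 8 lower in RPM, and 31 were higher and 20 lower after TMM scaling. Of the 25 higher calls, 14 were also called higher with TMM scaling and the block, among them miR-676-3p, miR-26b-5p, miR-15b-5p, miR-423-3p, miR-192-5p, miR-183-5p, miR-1198-5p, miR-99b-5p, miR-31-5p and miR-34a-5p.

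The number of higher calls was 13 without Chow-EV replicate 2, 15 without HFHC-EV replicate 1 and 15 without HFHC-EV replicate 2. Without both libraries numbered 1, or both numbered 2, limma called 0 miRNAs (20 higher and 6 lower, and 18 higher and 4 lower, at an unadjusted p under 0.05), while without both numbered 3 it called 39 higher and 5 lower.

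**Figure D2:**
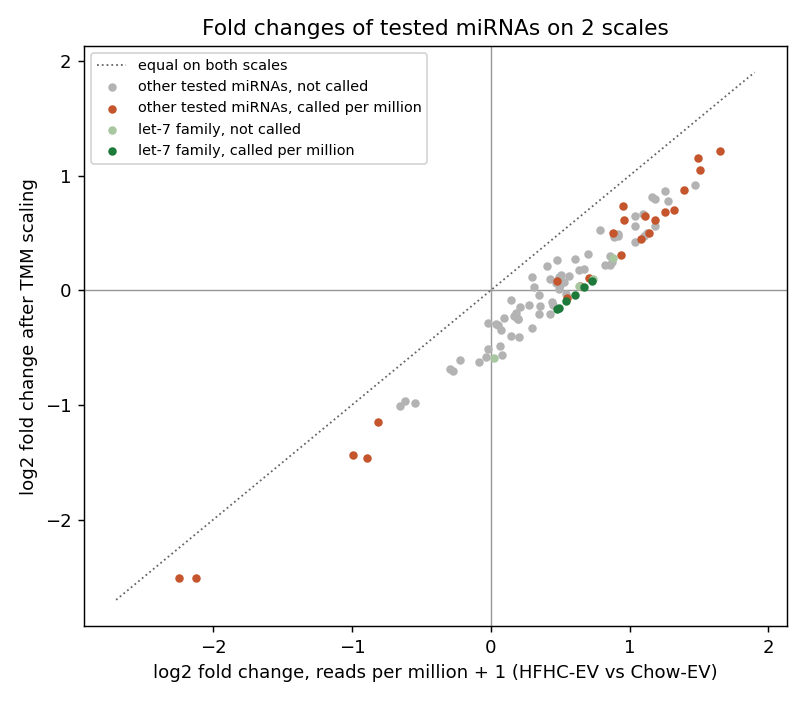
Log2 fold change of the 104 tested miRNAs in HFHC-EV against Chow-EV, on the per-million scale (x axis) and after TMM scaling (y axis), each point a miRNA. The points lie below the dotted line of equal values; the let-7 members in green are at or above 0 on the x axis and on both sides of 0 on the y axis.

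The hairpins of the named miRNAs were placed on GRCm38, the build that the submitters' processing notes name. Mir26b lies on chromosome 1 from 74394310 to 74394394 in an intron of Ctdsp1, a phosphatase gene, Mir15b on chromosome 3 from 69009772 to 69009835 in an intron of Smc4, a condensin gene, and Mir423 on chromosome 11 from 77078064 to 77078172 in an intron of Nsrp1. Mir676 lies on chromosome X from 100381097 to 100381185 in an intron of Eda, and Mir1198 on chromosome X from 7807101 to 7807221 in an intron of Gripap1. Mir192 (chromosome 19, 6264844 to 6264932) and Mir183 (chromosome 6, 30169668 to 30169737) overlapped no other annotated gene. Mir709 lies on chromosome 8 from 84086099 to 84086186 in an intron of Rfx1, and Mir30d on chromosome 15 from 68341208 to 68341289 in an exon of the lincRNA Gm20732. Mir99b lies on chromosome 17 from 17830188 to 17830257 in an intron of Spaca6, and Mir31 on chromosome 4 from 88910557 to 88910662 in an exon of a lincRNA. The mature let-7a-5p, let-7c-5p and let-7f-5p can each come from 2 hairpins, which cannot be told apart.

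miR-30a-3p was examined because the study followed it up; since its authors chose it on these libraries, its difference here is not independent evidence. It rose from 0.188 ± 0.131 RPM in Chow-EV to 1.25 ± 0.157 in HFHC-EV (n = 3 each), or from 11 to 72 reads, and was higher in all 3 HFHC-EV libraries than in any Chow-EV library. Its hairpin, Mir30a, lies on chromosome 1 from 23272269 to 23272339 and overlaps no other annotated gene. With a mean of 0.720 RPM it lay under the filter, so its test comes from the fit to all 422 miRNAs with reads, where its log2 fold change was 0.93 (SE 0.145, limma adjusted p = 0.0137). The adjusted p was 0.0507 with TMM scaling, 0.164 in edgeR's quasi-likelihood test on the recovered reads and 0.0505 without Chow-EV replicate 2, 0.0751 without both libraries numbered 1 and 0.119 without both numbered 2, in a range over all alternatives from 0.0037 to 0.164. With the replicate block it was 0.0172 with TMM scaling and 0.0037 in edgeR. The limma fit to all 422 miRNAs also called a provisionally named miRNA with 0 reads in Chow-EV and 3 in HFHC-EV. Its adjusted p was 0.0471 there and 0.40 in edgeR.

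miRNA families and groups fixed before the data were examined were then compared. In the let-7 family, 6 of 9 tested members rose in RPM (7 adjusted over the list alone), among them let-7a-5p, let-7b-5p, let-7c-5p, let-7d-5p and let-7f-5p, while after TMM scaling none rose and let-7b-5p, let-7d-5p and let-7f-5p had log2 fold changes below 0. let-7a-5p went from 141 ± 12.3 to 224 ± 17.3 RPM, and let-7i-5p stood at 55.6 ± 12.5 and 93.7 ± 23.4 (limma adjusted p = 0.0766). In the miR-30 family, 1 of 2 tested 5p products fell (miR-30d-5p; 1 adjusted over the list alone), and their summed share of miRNA reads was 0.826 ± 0.106% in Chow-EV and 0.324 ± 0.0228% in HFHC-EV. In the fit without the filter, 1 of 5 of these 5p products fell and 1 rose (the same over the list alone). The riser, chosen here after its values were seen, was miR-30c-5p, with 6 reads in Chow-EV and 38 in HFHC-EV (limma adjusted p = 0.0453, and 0.104 with TMM scaling). None of the 3p products passed the filter. In the fit without it, 1 of 6 rose and 1 fell, and the latter was miR-30c-2-3p, with 27 reads in Chow-EV and 1 in HFHC-EV. miR-30a-3p, chosen by the study, was the riser.

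Among miRNAs linked in the literature to cholesterol efflux and sterol regulation, 1 of 6 tested members rose, miR-26b-5p, and 3 did so adjusted over the list alone. Of those linked to steatosis, 2 of 12 rose (2 adjusted over the list alone): miR-192-5p and miR-34a-5p, a p53-induced miRNA, which went from 26.6 ± 2.75 to 52.0 ± 6.11 RPM. In the miR-99/100 and miR-125 group 2 of 6 rose, miR-125a-5p from 40.2 ± 3.69 to 67.2 ± 4.43 and miR-99b-5p from 49.8 ± 16.04 to 109.9 ± 31.8, although miR-125a-5p had a log2 fold change of 0.088 after TMM scaling. One of 4 members of the miR-15/16 family rose, miR-15b-5p. The counts adjusted over the list alone were the same for these 2 groups. In the miR-181 family 1 of 2 rose, also over the list alone, miR-181a-5p, whose log2 fold change turned from 0.55 to −0.068 with TMM scaling. None of the 3 tested members of the miR-17-92 group, of the 7 of the miR-23/27/24 clusters or of the 2 of the miR-29 family passed the threshold, nor did any adjusted over the list alone. Of these, miR-92a-3p stood at 19.3 ± 6.74 and 39.4 ± 6.37 RPM, miR-25-3p at 2.84 ± 2.33 and 4.80 ± 2.55, miR-24-3p at 84.2 ± 26.9 and 91.1 ± 38.5 and miR-23a-3p at 23.97 ± 14.9 and 51.6 ± 26.2. miR-29b-3p stood at 5.36 ± 3.08 and 7.45 ± 3.44, miR-29a-3p at 2.77 ± 3.88 and 4.79 ± 5.51, and miR-22-3p, abundant but in no list, at 60.5 ± 40.4 and 107 ± 60.7. The 1 tested member of the imprinted Dlk1-Dio3 cluster, miR-127-3p, stood at 2.95 ± 0.563 and 1.72 ± 0.541 (limma adjusted p = 0.107; lower over the list alone), and miR-411-5p, under the filter, at 0.0337 ± 0.0292 and 1.13 ± 0.319 (adjusted p = 0.0137 in the fit without it).

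With the replicate block, members that rose in RPM numbered 8 of the let-7 family, 5 of the cholesterol list, 8 of the steatosis list (1 fell), 5 of the miR-99/100 and miR-125 group, 4 of the miR-15/16 family, 2 of the miR-181 family, 3 of the miR-17-92 group, 4 of the miR-23/27/24 clusters and 2 of the miR-29 family, and miR-127-3p fell. With TMM scaling and the block these numbers were 0 (1 fell), 4, 5 (2 fell), 2 (1 fell), 3, 1, 1, 3 (2 fell) and 0 in the same order, and miR-127-3p fell. Among the miRNAs given with their values here, those called with the block (RPM) and not without it were miR-22-3p, let-7i-5p, miR-23a-3p, miR-451a, miR-92a-3p, miR-143-3p, miR-126a-3p, miR-29a-3p, miR-25-3p, miR-146a-5p, miR-127-3p and miR-29b-3p (limma adjusted p from 5.0e-31 to 0.0049), and miR-155-5p (adjusted p = 7.7e-04). The limma fit with the block had 2 residual degrees of freedom and 208 in total. Its p rest on a variance pooled over the tested miRNAs, not on the spread of each miRNA over the 3 pairs. Of the calls gained in RPM, let-7i-5p, miR-25-3p, miR-146a-5p, miR-29a-3p and miR-29b-3p were not called with TMM scaling and the block. There miR-146a-5p and miR-29b-3p had log2 fold changes of −0.030 and −0.11. In edgeR with the block, miR-143-3p, miR-92a-3p, miR-23a-3p and miR-127-3p were called and the others, miR-155-5p left aside, were not. With TMM scaling and the block, miR-24-3p and miR-342-5p were called lower (log2 fold changes of −0.56 and −0.49, limma adjusted p = 3.4e-05 and 0.0069), as they were in edgeR with the block (adjusted p = 0.0024 and 0.0207).

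Camera called 0 of the 9 lists with 3 or more tested members. The lowest camera adjusted p was 0.199, for the let-7 family (up) and the haematopoietic list (down). Unadjusted, these 2 lists were under 0.05 (lowest camera unadjusted p = 0.0225). fry likewise called 0 lists (3 at an unadjusted p under 0.05), and with an estimated correlation in camera every adjusted p was 0.824. With the replicate block, camera called 1 list, the let-7 family (adjusted p = 0.0034 in RPM, adjusted p = 0.719 with an estimated correlation), and after TMM scaling with the block its direction was down (adjusted p = 0.637). With the block in RPM, fry called 7 of the 9 lists (adjusted p from 0.0049 to 0.0434), all but the erythroid (0.109) and haematopoietic (0.276) lists; fry does not set a list against other miRNAs. Camera sets the t statistics of a list, not its fold changes, against those of the other miRNAs. Besides the haematopoietic list (median log2 fold change −0.022), its direction was down for the steatosis, erythroid and miR-23/27/24 lists. The median log2 fold changes of the steatosis, erythroid and miR-23/27/24 lists were 0.58, 0.19 and 0.86, against 0.51 over all tested miRNAs. The erythroid list reached 3 tested members only with miR-486a-5p and miR-486b-5p, whose values were identical in every library.

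Groups marking hepatocytes and other cell types were compared in the same way. Of 2 tested hepatocyte-enriched miRNAs, 1 rose (miR-192-5p; 1 adjusted over the list alone), while miR-122-5p stood at 4.13 ± 5.56 RPM in Chow-EV and 5.32 ± 7.50 in HFHC-EV (limma adjusted p = 0.934). In the fit without the filter, 2 of 10 rose and 1 fell (2 and 2 over the list alone). The faller, chosen here after its values were seen, was miR-194-2-3p, with 69 reads in Chow-EV and 18 in HFHC-EV. Its limma adjusted p was 0.0295, and 0.0507 with TMM scaling. None of the tested members of the erythroid (3), haematopoietic (5), endothelial (1) and mesenchymal (1) lists passed the threshold, and no member of the miR-200 or the muscle and neuronal lists passed the filter. Of the erythroid members, miR-486a-5p and miR-486b-5p held identical values in every library and are in effect 1 measurement. The 1 mesenchymal member was called over the list alone. It was miR-143-3p, at 0.543 ± 0.662 and 2.30 ± 0.730 RPM (limma adjusted p = 0.0695). With the block, 1 haematopoietic member rose and 2 fell, and 1 member each of the erythroid, endothelial and mesenchymal lists rose. With TMM scaling and the block, 0 haematopoietic members rose and 3 fell, and 1 member each of the other 3 lists rose. Of the immune miRNAs, miR-146a-5p stood at 7.885 ± 5.81 and 11.4 ± 6.63 and miR-342-5p at 5.41 ± 0.207 and 5.72 ± 0.585. The erythroid miR-486b-5p stood at 2.68 ± 2.53 and 3.15 ± 2.74, and the endothelial miR-126a-3p at 2.59 ± 2.77 and 5.27 ± 3.71. The remaining marker miRNAs lay under the filter: miR-126a-5p had 4 and 4 reads in Chow-EV and HFHC-EV, miR-145a-5p 8 and 11, miR-429-3p 46 and 30, miR-141-3p 4 and 2, miR-9-5p 32 and 53, and miR-375-3p 11 and 24.

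Blood-cell miRNAs marked the libraries numbered 1 in both diets. The erythroid miR-451a stood at 101.7 RPM in Chow-EV replicate 1 against at most 1.76 in the other Chow-EV libraries, and at 135.5 in HFHC-EV replicate 1 against at most 9.90. The erythroid list as a whole took 7.41% and 6.199% of the miRNA reads in these libraries. The myeloid miR-223-3p stood at 3.12 in Chow-EV replicate 1 and 3.18 in HFHC-EV replicate 1, and at most at 0.398 and 0.314 in the others. The libraries numbered 3 held miR-204-5p at 30.9 (Chow-EV) and 98.0 (HFHC-EV) RPM against at most 0.768 and 0.261, and miR-149-5p at 14.6 and 41.0 against at most 0.051 and 0.052; these were chosen after their values were seen. Of all miRNAs with at least 20 reads in both libraries of a number, 4 were in both diets at least 4 times as high in number 1 as in the other libraries of the same diet, 0 in number 2 and 25 in number 3. miR-486a-5p and miR-486b-5p held identical values in every library, as reads shared between near-identical copies would give.

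**Figure D3:**
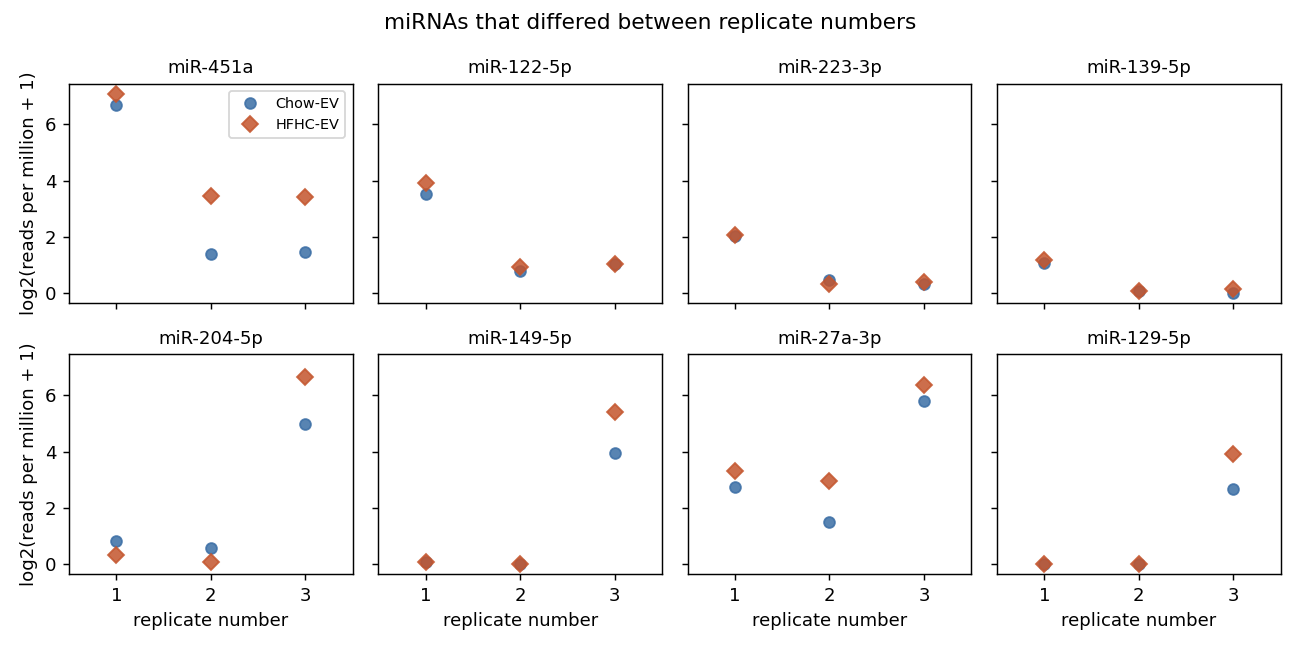
Abundance of 8 miRNAs as log2(RPM + 1) by replicate number, Chow-EV as blue circles and HFHC-EV as orange diamonds, each point 1 library. miR-451a, miR-122-5p, miR-223-3p and miR-139-5p are highest in the libraries numbered 1 of both diets, and miR-204-5p, miR-149-5p, miR-27a-3p and miR-129-5p in those numbered 3.

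The last comparison asked whether the 5p and 3p products of 1 hairpin moved apart between the diets. In the miR-151 hairpin, miR-151-5p went from 9.33 ± 0.290 to 15.9 ± 1.12 RPM while miR-151-3p went from 2.31 ± 0.0211 to 1.74 ± 0.0828 (n = 3 each). In the miR-423 hairpin the larger change was on the other arm: miR-423-3p went from 15.2 ± 1.71 to 39.2 ± 1.94 and miR-423-5p from 2.84 ± 0.395 to 3.88 ± 0.234. The log2 fold change of the 3p product minus that of the 5p product was −0.98 for miR-151 (limma diffSplice, adjusted p = 6.2e-05) and 0.97 for miR-423 (adjusted p = 5.9e-04), and these were 2 of the 8 hairpins tested. With pseudocounts of 0.1 and 10 this difference was −1.15 and −0.49 for miR-151, and 0.92 and 0.86 for miR-423. Mir151 lies on chromosome 15 from 73254815 to 73254882 in an intron of Ptk2, the gene of focal adhesion kinase. With TMM scaling both adjusted p were 0.0495, and scaling to total miRNA reads or to the upper quartile called 0 of 8 (2 and 0 at an unadjusted p under 0.05). With the replicate block 5 hairpins were called, the others being miR-23a, miR-23b and let-7d, and without both libraries numbered 1 limma called 0 (2 at an unadjusted p under 0.05).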

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

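TMM scaling, TMM with the block, edgeR, fry with the block, the correlations over pairs of different numbers and in RPM and the fits without both libraries of a replicate number were chosen after the data were seen. miRNAs called higher and lower in HFHC-EV numbered 25 and 5 in limma. Higher calls numbered 2 with RLE scaling, 1 scaled to total miRNA reads, 1 with TMM scaling, 2 with TMM scaling without the 5 most abundant miRNAs and 1 in edgeR. With upper-quartile scaling limma called 0 higher and 2 lower (5 and 10 at an unadjusted p under 0.05), DESeq2 called 7 and 12, and voom 0 and 0 (8 and 13 at an unadjusted p under 0.05). Without the filter 60 were higher and 22 lower of 422 tested, and with a mean of 50 or more reads 3 were lower of 73 tested. The calls without the filter included a miRNA with 0 against 3 reads. A log2 fold change of at least 1 left 14 and 2 at an unadjusted p under 0.05 and 10 and 2 at an adjusted p under 0.05. The block gave 69 higher and 8 lower, with TMM scaling 31 and 20, and in edgeR 25 and 20. Without 1 library or 1 replicate number, higher calls lay between 0 and 39 and lower calls between 0 and 5. miR-30a-3p stayed higher in HFHC-EV in every setting that tested it, but was not past the threshold scaled to total miRNA reads (log2 fold change 0.71), with upper-quartile (0.72) or TMM scaling (0.72), or in edgeR (2.03, and 2.70 with the authors' denominator). Without libraries its log2 fold change lay between 0.84 and 1.00, and with a mean of 50 or more reads it was not tested. It was also not past the threshold without Chow-EV replicate 2, without both libraries numbered 1 or without both numbered 2. Camera called 0 lists, but 1, the let-7 family, without the filter (adjusted p = 0.0278) and 1, again the let-7 family, with the block (adjusted p = 0.0034, and 0.719 with an estimated correlation), and fry with the block called 7. Robust variance does not enter camera. Hairpins called numbered 2, against 0 scaled to total miRNA reads, 0 with upper-quartile scaling, 13 without the filter, 1 with a mean of 50 or more reads, 5 with the block on either scale, and between 0 and 5 without libraries. Without 1 library, the difference in detected miRNAs lay between −12.3 and 32.0, that in the share of the 10 most abundant between −3.79 and 1.04 percentage points (0.53 for the 20 most abundant), that in the share of miR-122-5p between −0.229 and 0.165, and that of correlations between −0.0079 and 0.0557 (−0.0036 on log2(RPM + 1)). Total miRNA reads were higher in HFHC-EV in each setting tried for them. Apart from the numbers of miRNAs tested and of libraries left, the cause of these changes was not tested.

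Of the values of the 47 miRNAs followed singly besides miR-30a-3p, over all settings, 802 had the same direction and side of the threshold, 203 lost the call, 31 gained it and 161 had the other direction. Among these 47 alone, the block in RPM gained 12 calls and ended 0, and against the same fit without the block it gained 16 higher and 3 lower calls with TMM scaling and 14 and 5 in edgeR and ended 0. Of the values in the other direction, 5 were past the threshold: miR-24-3p in DESeq2 (adjusted p = 0.0276), and miR-24-3p and miR-342-5p with TMM scaling and the block and in edgeR with the block. The log2 fold change had the other direction as follows, and the cause was not tested. With RLE scaling it was −0.013 for let-7a-5p, −0.20 for let-7f-5p, −0.076 for let-7b-5p, −0.60 for miR-24-3p, −0.14 for let-7d-5p, −0.25 for miR-122-5p, −0.064 for miR-146a-5p, −0.52 for miR-342-5p, −0.27 for miR-486b-5p, −0.044 for miR-126a-5p, −0.041 for miR-145a-5p, −0.027 for miR-9-5p, −0.14 for miR-29b-3p, −0.10 for miR-181a-5p. Scaled to total miRNA reads it was −0.010 for let-7a-5p, −0.19 for let-7f-5p, −0.073 for let-7b-5p, −0.60 for miR-24-3p, −0.13 for let-7d-5p, −0.25 for miR-122-5p, −0.062 for miR-146a-5p, −0.52 for miR-342-5p, −0.27 for miR-486b-5p, −0.047 for miR-126a-5p, −0.043 for miR-145a-5p, −0.028 for miR-9-5p, −0.14 for miR-29b-3p, −0.10 for miR-181a-5p. With upper-quartile scaling it was −0.043 for let-7a-5p, −0.23 for let-7f-5p, −0.11 for let-7b-5p, −0.63 for miR-24-3p, −0.17 for let-7d-5p, −0.24 for miR-122-5p, −0.086 for miR-146a-5p, −0.54 for miR-342-5p, −0.28 for miR-486b-5p, −0.048 for miR-126a-5p, −0.043 for miR-145a-5p, −0.069 for miR-9-5p, −0.17 for miR-29b-3p, −0.13 for miR-181a-5p. With TMM scaling, without and with the block it was −0.16 for let-7f-5p, −0.038 for let-7b-5p, −0.56 for miR-24-3p, −0.10 for let-7d-5p, −0.23 for miR-122-5p, −0.030 for miR-146a-5p, −0.49 for miR-342-5p, −0.25 for miR-486b-5p, −0.043 for miR-126a-5p, −0.035 for miR-145a-5p, −0.014 for miR-9-5p, −0.11 for miR-29b-3p, −0.068 for miR-181a-5p. With TMM scaling without the 5 most abundant miRNAs it was −0.026 for let-7c-5p, −0.084 for let-7a-5p, −0.27 for let-7f-5p, −0.15 for let-7b-5p, −0.67 for miR-24-3p, −0.21 for let-7d-5p, −0.012 for let-7i-5p, −0.30 for miR-122-5p, −0.13 for miR-146a-5p, −0.58 for miR-342-5p, −0.32 for miR-486b-5p, −0.047 for miR-126a-5p, −0.047 for miR-145a-5p, −0.049 for miR-9-5p, −0.20 for miR-29b-3p, −0.17 for miR-181a-5p, −0.020 for miR-125a-5p. In DESeq2 it was −0.020 for let-7a-5p, −0.20 for let-7f-5p, −0.080 for let-7b-5p, −0.59 for miR-24-3p, −0.14 for let-7d-5p, −0.15 for miR-146a-5p, −0.63 for miR-342-5p, −0.45 for miR-486b-5p, −0.63 for miR-126a-5p, −0.14 for miR-145a-5p, −0.18 for miR-29b-3p, −0.11 for miR-181a-5p. In voom it was −0.16 for let-7f-5p, −0.034 for let-7b-5p, −0.56 for miR-24-3p, −0.10 for let-7d-5p, −0.49 for miR-122-5p, −0.0064 for miR-146a-5p, −0.55 for miR-342-5p, −0.46 for miR-486b-5p, −0.31 for miR-126a-5p, −0.32 for miR-145a-5p, −0.44 for miR-9-5p, −0.14 for miR-29b-3p, −0.064 for miR-181a-5p. In edgeR it was −0.16 for let-7f-5p, −0.043 for let-7b-5p, −0.55 for miR-24-3p, −0.10 for let-7d-5p, −0.22 for miR-122-5p, −0.11 for miR-146a-5p, −0.59 for miR-342-5p, −0.045 for miR-451a, −0.41 for miR-486b-5p, −0.80 for miR-126a-5p, −0.34 for miR-145a-5p, −0.14 for miR-29b-3p, −0.076 for miR-181a-5p. In edgeR with the block it was −0.16 for let-7f-5p, −0.038 for let-7b-5p, −0.57 for miR-24-3p, −0.10 for let-7d-5p, −0.32 for miR-122-5p, −0.042 for miR-146a-5p, −0.57 for miR-342-5p, −0.37 for miR-486b-5p, −0.35 for miR-126a-5p, −0.29 for miR-145a-5p, −0.10 for miR-9-5p, −0.14 for miR-29b-3p, −0.070 for miR-181a-5p. Over the fits without 1 library or 1 replicate number it lay between −0.24 and 0.35 for miR-24-3p, −0.80 and 1.03 for miR-122-5p, −0.023 and 0.12 for miR-342-5p, −0.31 and 0.72 for miR-486b-5p, −0.063 and 0.10 for miR-126a-5p, −0.069 and 0.18 for miR-145a-5p, −0.44 and 0.21 for miR-429-3p, −0.087 and 0.048 for miR-141-3p, −0.32 and 0.57 for miR-9-5p, −0.055 and 0.41 for miR-375-3p, −0.042 and 1.51 for miR-29a-3p.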

Other observations

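The tests in this part, and the miRNAs named in its first paragraph, were chosen after the results were seen. Several miRNAs under the filter of 1 RPM differed between the diets in the limma fit to all 422 miRNAs with reads. That fit also called a difference of 0 against 3 reads, in a provisionally named miRNA. miR-330-3p had no read in Chow-EV and 1.20 ± 0.103 RPM in HFHC-EV (n = 3, 69 reads, limma adjusted p = 0.0066), at least 23.6-fold higher with 3 reads over the group as the floor. miR-130b-5p went from 1 to 61 reads, miR-350-3p from 3 to 62, miR-28a-3p from 2 to 65 and miR-103-3p, which is linked to insulin signalling, from 2 to 57. In the other direction, miR-193b-5p had 51 reads in Chow-EV and 0 in HFHC-EV (at least 16.6-fold lower), miR-12185-5p 42 and 0 (at least 13.7-fold lower) and miR-706 39 and 0 (at least 12.7-fold lower). Each of these had an adjusted p under 0.05 with TMM scaling as well, and none did in edgeR (0.0558 to 0.0840).

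More miRNAs were called higher (25) than lower (5) in RPM. A difference in sequencing depth is argued against by the ratio of the denominators, 0.974 (HFHC-EV over Chow-EV). The summed signal without the 10 most abundant miRNAs was still 1.64 times as high in HFHC-EV. The higher sum thus did not rest on those 10 alone. All listed miRNAs took at most 0.344% of a denominator, so a few abundant ones could hardly move the RPM of the others. A shared shift in the share of miRNA among all reads could account for the 6 called let-7 members, whose largest absolute log2 fold change after TMM scaling was 0.16 and none of which was called with TMM scaling and the block. As the cause of all 25 it is argued against in the fits with the block that scale the libraries to each other. With TMM scaling and the block, 14 of the 25 were called higher. edgeR with the block called 25 miRNAs higher and 20 lower, and 18 of its calls were among the 30 in RPM. With TMM scaling and no block, 1 of the 25 was called higher, and 1 in edgeR without the block. DESeq2 without the block called 7 miRNAs higher and 12 lower, and 11 of its calls were among the 30 in RPM. The fits without the block thus differ and leave it open. Whether the shift itself came from the diet, from the vesicle yield or from other small RNA in the denominator stays open, and no value here decides it.

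Libraries of different diets with the same replicate number deviated together from their diet means. A correlation across miRNAs takes out most of the scale of a whole library by itself. TMM scaling, after which the lowest correlation was 0.895, is therefore a weak test of a shared scale. The values show that same-number libraries shared differences between miRNAs, beyond a scale of the whole library. Blood-derived RNA may have contributed to the libraries numbered 1: of 10 erythroid, haematopoietic and endothelial list members with at least 0.1 RPM (miR-486a-5p and miR-486b-5p, with identical values, counted once, a choice made after the first result), 7 were highest in number 1 of both diets, against 47 of 238 other miRNAs (2-sided Fisher exact p = 0.0012, across miRNAs, which are not independent), with miR-451a at 101.7 and 135.5, miR-146a-5p at 14.5 and 18.8 and miR-126a-3p at 5.73 and 9.39 RPM; hepatocyte miR-122-5p was highest there too. Without those members the correlations were 0.941, 0.899 and 0.945 for the numbers 1, 2 and 3, which argues against these members as the whole cause. Any blood-derived miRNAs outside the lists stayed in, so blood as the cause in number 1 is not excluded. A shared isolation day or batch cannot be told apart from other causes, since the labels name none and the correlation, at least 0.894, would be the same; a pairing of mice stays open too.

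The 10 possible splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 25 higher and 5 lower miRNAs and the highest other split 0 and 0 (1 of the 10 splits as large for each), and the 3 other splits that part all 3 same-number pairs also gave 0. For hairpins the real split gave 2 and the highest other 1 (1 of 10 as large), and for lists 0 and 3 (10 of 10). These highest values came from splits that part 1 same-number pair, and the 3 other splits that part all 3 pairs gave 0 hairpins and 0 lists.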
